A study of Mus musculus with 28 samples.

How the data were processed

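Gene expression was measured on 28 Affymetrix mouse arrays, 1 per sample part: TRP1-specific CD4+ T cells of the Th1 or Th17 type at day 0, day 5 and day 15 after transfer, without or with 2 h of restimulation. The values were deposited by the authors as log2 RMA values, made in Affymetrix Expression Console, and the versions are not given in the sources used here. RMA corrects background, equalises the distributions of the arrays and summarises the probes of each probe set. Which arrays were normalised together is not stated, and array medians ran from 6.77 to 7.09. The unit was checked on the values, which all lie on a log2 scale. No further normalisation was applied for the values in the report.

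Of 35556 probe sets, 21789 carried 1 gene symbol, 1621 several and 12146 none here, and only the first kind was used. The gene table held the identifier of 21698 of these, and 0 symbols were updated. Where a gene had more than 1 probe set (999 genes) the one with the highest mean was taken, leaving 19938 genes. Correlations between arrays of a group ran from 0.987 to 0.998.

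A linear model with 1 coefficient per group was fitted to the 24 arrays taken after transfer, in 8 groups, with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 16 residual degrees of freedom. Groups of 2 to 4 arrays thus shared a common estimate of spread. The 10 pairwise comparisons were Th17 against Th1 at each day and condition, restimulated against unstimulated for each type and day, and day 15 against day 5 for each type. There were 3 interactions: polarization with day among unstimulated groups, and polarization with restimulation at each day. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and the count changing at least 2-fold is given beside it. The 4 day 0 arrays were left out of the model, having 1 array per group, and are given as values.

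The 24 gene lists cover the Th17 and Th1 programs, Wnt and stem-like memory, cytotoxic and terminal effector, pro-apoptotic and anti-apoptotic genes, inhibitory receptors, Treg, Tfh and Th2 genes, and cell cycle genes. They also cover early genes induced by the T cell receptor, cytokines and chemokines, type I interferon response, homing and adhesion, glycolysis, cholesterol synthesis, heat shock and handling stress, and markers of B, myeloid, dendritic, erythroid, NK and CD8 T cells. Lists, groups, tests, alternative settings and the rule for naming genes were fixed before the data were examined. Of 333 list entries 299 were matched to a measured gene. Each list was tested by camera in limma with a preset correlation between genes of 0.01, adjusted over the 24 lists of a comparison, and again with the correlation estimated for each list. Members were counted as called over all genes and as called when adjusted over the list alone. At day 0 the median of a list was ranked among 10000 random lists matched on expression in 50 bins.

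Named genes are, for each pairwise comparison, up to 10 each way with the largest log2 changes among called genes whose groups do not overlap, leaving out clone names and probe sets of several genes. To these come a panel of genes whatever their change, of which 14 are named here, and up to 4 called members of each list with the largest change. For interactions they are up to 5 called genes each way and the panel, and at day 0 up to 10 each way among genes above the median of expression and the panel. Within the rule, genes are described in the report mainly where their call did not depend on a single array, a choice made after their values were seen. The other panel genes are not reported here.

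Whether the replicate numbers pair arrays was checked by correlating the deviations of same-numbered arrays from their group means over 9969 genes. They did at day 5 for restimulation in Th1 (0.16 to 0.22) and Th17 (0.38 to 0.47) and for restimulated Th17 against Th1 (0.22 to 0.48), so these were also fitted with the replicate as a block. The block was run as an alternative for the other pairwise comparisons and the interactions with restimulation too. Where only 1 compared array held a number, the block took that array out of the comparison. Other alternatives were a model of only the compared groups, genes above the median, cyclic loess, centring on array medians, the mean of all probe sets of a gene, a prior with trend and robust settings, array weights, a random block for sample parts and leaving out each array in turn. Where this left 1 array in a group, that array was assumed to vary like the others. Covariates for myeloid and erythroid marker means, and leaving out both parts of Th17 sample 1 of day 5, were added after seeing the data.

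The pipeline was tested on simulated data with 200 of 19938 genes changed. At a log2 change of 1, between 72 and 98% were recovered over the 13 contrasts, the lowest being the day 15 interaction with restimulation. At a change of 2, between 98 and 100% were recovered, and 6 to 16 unchanged genes were called. Genes were drawn independently and with the same spread on every array, so these rates do not cover correlated genes or arrays of unequal quality. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.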

Results

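To follow CD4+ T cells of the Th1 and Th17 helper types after transfer into mice, gene expression was measured on 28 arrays. The cells carried a transgenic T cell receptor that recognises TRP1, a protein of melanocytes, and were polarised in culture before transfer. They were profiled on the day of transfer, day 0, and again on day 5 and day 15 after recovery from pooled spleens and inguinal lymph nodes of irradiated recipients. Each sample was divided: one part was restimulated for 2 h with antibodies to CD3 and CD28, the other was left unstimulated. Arrays are named here by type, day and replicate number. The labels do not state that equal numbers mark parts of 1 sample. Day 5 held 3 Th1 and 3 Th17 samples, day 15 held 2 Th1 and 4 Th17 samples, and day 0 held 1 array per group, so no spread is known there. The median of all probe sets lay between 6.77 and 7.09 log2 units on every array, and the number of arrays limits the precision. No detection calls are used here, so levels under these medians are not shown to be above background. Folds of Il2, Il17a, Il17f and Il23r against such levels compare RMA values, not transcript amounts. The labels do not say that replicates came from separate mice, so p-values measure only the spread between these samples. For each gene given with a mean ± SD and an adjusted p under 0.05, all arrays of one group lay above all arrays of the other unless stated.

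Day, restimulation and polarization each set arrays apart in a principal component analysis over 9969 genes. The first component held 33.1% of the variance, with the day 0 arrays at 26.46 to 61.60 and all others at -22.70 to 12.43. On the second, with 21.9%, every unstimulated array taken after transfer lay at 4.67 to 19.94 and every restimulated one taken after transfer at -37.74 to -2.32. On the third, with 15.6%, all Th1 arrays of day 5 lay at 19.42 or more, Th17 arrays of day 5 between -0.11 and 11.80, and all arrays of day 15 at -3.31 or less.

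**Figure D1:**
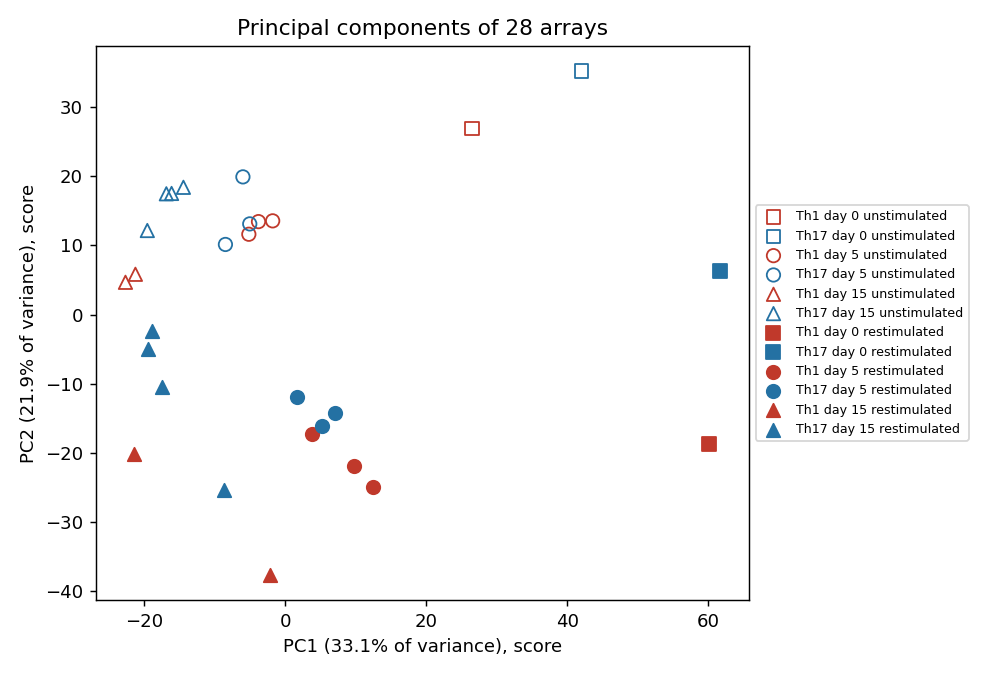
Scores of the 28 arrays on the first 2 principal components (33.1% and 21.9% of the variance, arbitrary units) over 9969 genes. Red marks Th1 and blue Th17, filled symbols are restimulated arrays and the symbol shape gives the day: the day 0 arrays lie at 26.46 or more on the first axis.

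The first comparison asked how Th17 cells differed from Th1 cells after 5 days in the host without restimulation. Il23r (probe set 10545154), a receptor chain for the cytokine that sustains Th17 cells, was 9.71-fold higher in Th17 cells, at 9.16 ± 0.26 against 5.88 ± 0.11 log2 units (SD, n = 3 each, limma adjusted p = 7.29e-12). Klrg1 (probe set 10547590), a receptor of terminally differentiated effector cells, was 9.25-fold lower, at 7.79 ± 0.30 against 11.00 ± 0.07 (adjusted p = 7.29e-12). Ccr7 (probe set 10390763), which guides T cells into lymph nodes, was higher in Th17 cells, at 10.97 ± 0.32 against 9.09 ± 0.32 (adjusted p = 2.27e-06). Il7r, a chain of the receptor for the survival cytokine IL-7, was higher too, at 12.27 ± 0.39 against 10.97 ± 0.09 (adjusted p = 1.66e-05). The signature cytokine genes did not pass the test in these unstimulated cells, with log2 differences, Th17 minus Th1, of -0.52 for Ifng (adjusted p = 0.538), 0.49 for Il17a (adjusted p = 0.565) and 0.35 for Il17f (adjusted p = 0.393).

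Of the 14 measured genes of the Wnt and stem-like memory list, 7 were higher in Th17 cells at day 5 and 0 lower, the same counts as when adjusted over the list alone. Beside Ccr7 and Il7r they included Bach2 (log2 difference 1.09) and Id3 (0.99), regulators that restrain effector differentiation. Ctnnb1, which encodes beta-catenin, stood at -0.06 (adjusted p = 0.891). The list as a whole was higher (adjusted p = 6.94e-10 by camera, adjusted p = 0.0319 with an estimated correlation). Bcl2, a survival gene, was higher by 1.05. In the cytotoxic and terminal effector list 7 of 17 genes were lower in Th17 cells and 1 was higher (8 and 1 adjusted over the list alone), but without Th17 sample 3 the lower ones numbered 4. Examples were Zeb2 at -1.70, Klrk1 at -1.20 and Gzma at -1.15. Gzmb, which encodes granzyme B, stood at -0.09 (adjusted p = 0.935). This list was lower (adjusted p = 1.27e-08), with an adjusted p = 0.0824 with an estimated correlation. From the Th17 program 3 of 12 genes were higher, namely Il23r, Ccr6 (2.21) and the transcription factor gene Rora (1.61), and 0 were lower (3 and 1 adjusted over the list alone, adjusted p = 0.000275, adjusted p = 0.167 with an estimated correlation). No cell cycle gene of 24 passed alone with limma, yet as a list they lay lower in Th17 cells, with a median of -0.22 (adjusted p = 1.26e-05, adjusted p = 0.482 with an estimated correlation). Homing and adhesion genes were higher in 3 of 15 and lower in 1 (6 and 2 adjusted over the list alone, adjusted p = 0.000586, adjusted p = 0.0542 with an estimated correlation). Outside the lists, the largest differences included Pcsk1, a protease that processes prohormones, at 3.46, and Klk1b11 at -4.03, a kallikrein gene with close relatives that its probes may also detect.

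Genes of granulocytes were higher in the Th17 samples as well. Lcn2, which encodes an iron-binding protein of neutrophils, stood at 10.50 ± 1.41 against 6.97 ± 0.43 (adjusted p = 0.00145), and S100a8, an abundant neutrophil gene, at 9.03 ± 1.36 against 6.07 ± 0.10 (adjusted p = 0.000923). Of the 14 myeloid markers 3 were higher (5 adjusted over the list alone, adjusted p = 8.88e-06, adjusted p = 0.347 with an estimated correlation), 1 without any 1 of the Th1 samples or Th17 sample 1 and 5 without Th17 sample 2. Their mean was 8.38 in Th17 sample 1, 7.12 and 7.32 in the other two, and 6.72 to 6.99 in the Th1 samples. Erythroid markers lay higher by a median of 0.14 (1 of 6 with limma and adjusted over the list alone, adjusted p = 0.038, adjusted p = 0.482 with an estimated correlation), a call lost without Th1 samples 1 (adjusted p = 0.0576) or 3 (0.0872) or Th17 sample 1 (0.0829). Across all 19938 genes, limma called 724, of which 460 were higher and 264 lower in Th17 cells (1063 and 1096 with array weights), and 165 differed at least 2-fold. The count was 444 without Th1 sample 1, 447 without Th1 sample 3, 481 without Th17 sample 1, 482 without Th17 sample 3, 2159 with array weights and 427 with the myeloid marker mean as a covariate.

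**Figure D2:**
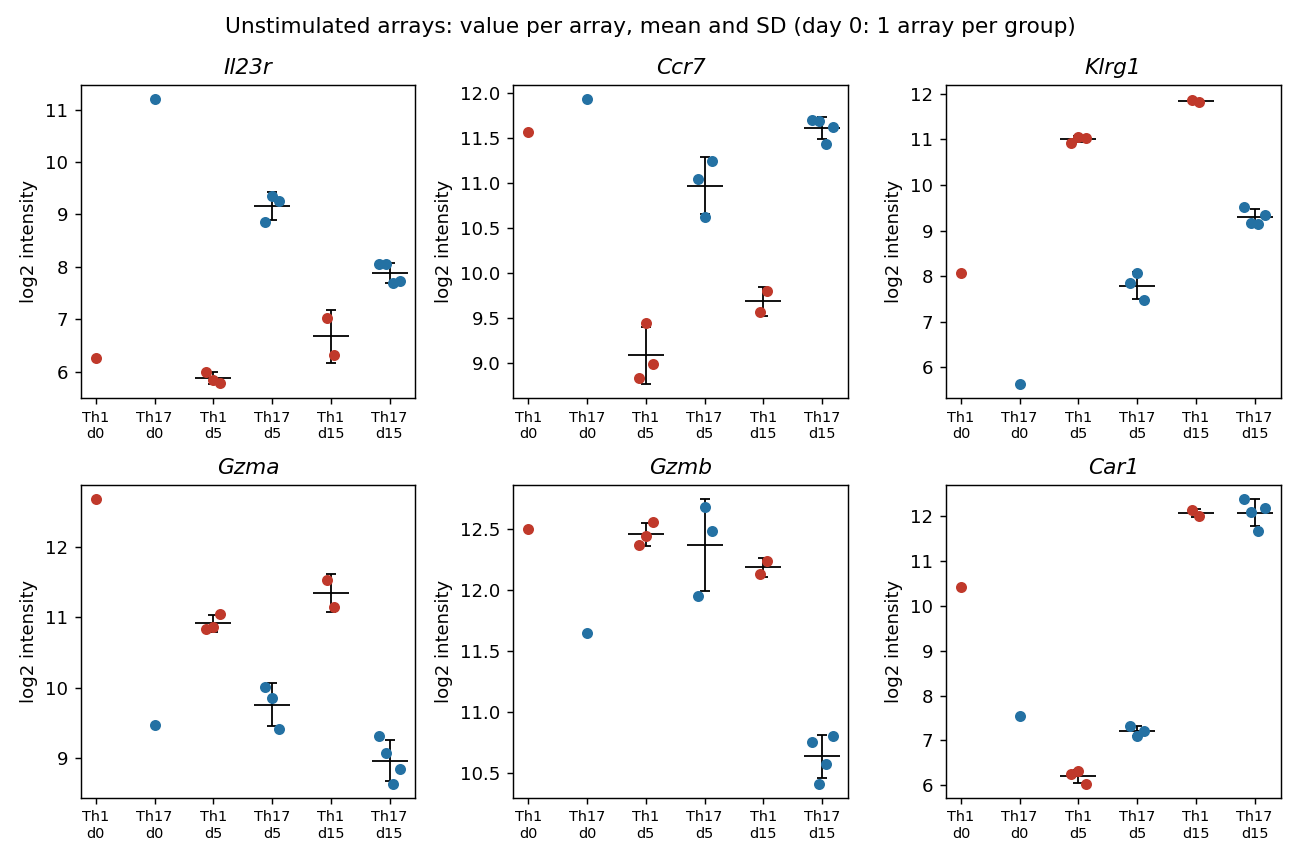
Log2 expression of Il23r, Ccr7, Klrg1, Gzma, Gzmb and Car1 in unstimulated arrays at day 0, day 5 and day 15. Red marks Th1 and blue Th17, each symbol is 1 array and the black bar is the mean ± SD: Klrg1 averages 11.00 in Th1 and 7.79 in Th17 cells at day 5, and Gzmb 12.18 and 10.63 at day 15.

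The restimulated parts of the day 5 samples were compared to see which inducible genes set the types apart. Il17a (probe set 10345032), the cytokine gene that names the Th17 type, stood at 10.27 ± 0.05 in Th17 and 6.49 ± 0.04 in Th1 cells, a 13.7-fold difference (n = 3 each, adjusted p = 8.88e-09). Its relative Il17f (probe set 10353415) was 9.58-fold higher in Th17 cells, at 9.94 ± 0.26 against 6.68 ± 0.05 (adjusted p = 7.35e-12). Il4, a cytokine gene of Th2 cells, was lower in Th17 cells, at 7.08 ± 0.73 against 9.95 ± 0.73 (adjusted p = 0.000261). Ifng, the signature Th1 cytokine gene, stood at 13.01 ± 0.09 in Th17 and 13.36 ± 0.19 in Th1 cells (adjusted p = 0.824), and Il2, which encodes a T cell growth factor, at 11.67 ± 0.26 and 11.70 ± 0.55 (adjusted p = 0.998). Il23r (3.39), Ccr7 (2.19) and Il7r (1.42) were higher in Th17 cells here too, and Klrg1 (-3.00) was lower.

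From the Th17 program 6 of 12 genes were higher in restimulated Th17 cells and 0 lower (6 and 1 adjusted over the list alone, adjusted p = 2.74e-11, adjusted p = 0.0105 with an estimated correlation). The Wnt and stem-like memory list had 8 of 14 genes higher and 0 lower (9 and 0 adjusted over the list alone, adjusted p = 3.1e-11, adjusted p = 0.0105 with an estimated correlation), and 5 without Th1 sample 3, Th17 sample 1 or Th17 sample 3. Its members included Bach2 at 1.07 and Lef1, a partner of beta-catenin, at 0.53. In the cytotoxic list 5 of 17 genes were lower and 1 was higher (8 and 1 adjusted over the list alone, adjusted p = 2.59e-10, adjusted p = 0.0361 with an estimated correlation), among them Zeb2 (-1.37) and Gzma (-1.07). Of the 7 Th2 genes 4 were lower, Il4 among them, and the chemokine receptor gene Ccr4 was higher at 1.41 (5 and 1 adjusted over the list alone, adjusted p = 6e-05, adjusted p = 0.021 with an estimated correlation). The lower Th2 genes numbered 2 without Th1 sample 3 or Th17 sample 2. The myeloid marker mean was 7.81 in restimulated Th17 sample 1, 6.66 and 6.85 in the other two, and 6.50 to 6.61 in Th1 samples. That list was higher (1 of 14 with limma, 3 higher and 1 lower adjusted over the list alone, adjusted p = 0.00909, adjusted p = 0.55 with an estimated correlation), but not without Th17 sample 1 (adjusted p = 0.718). The higher ones numbered 0 without Th1 samples 1 or 3 or Th17 sample 1 and 2 without Th17 sample 2. In all, 793 genes were called, 589 higher and 204 lower in Th17 cells, with 170 at least 2-fold. Without Th1 sample 3 it was 488 genes, and 503 without Th17 sample 3.

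By day 15 the unstimulated cells were compared again to ask what remained of the difference. Gzma (probe set 10412211), which encodes granzyme A, was 5.21-fold lower in Th17 cells, at 8.96 ± 0.29 (n = 4) against 11.34 ± 0.27 (n = 2, adjusted p = 5.81e-09), and Gzmb (probe set 10420308) was 2.93-fold lower, at 10.63 ± 0.18 against 12.18 ± 0.08 (adjusted p = 2.68e-05). Dapl1 (probe set 10472235) was 10.4-fold higher in Th17 cells, at 11.48 ± 0.22 against 8.10 ± 0.18 (adjusted p = 4.67e-09), and Ccr7 3.81-fold higher, at 11.61 ± 0.13 against 9.68 ± 0.16 (adjusted p = 4e-06). Il23r differed by 1.22, at 7.89 ± 0.19 against 6.67 ± 0.51 (adjusted p = 0.000111). Il17a (0.21, adjusted p = 0.84), Il17f (0.05, adjusted p = 0.941) and Ifng (-0.93, adjusted p = 0.123) did not pass the test.

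In the cytotoxic and terminal effector list 14 of 17 genes were lower in Th17 cells at day 15 and 0 higher (15 and 0 adjusted over the list alone, adjusted p = 4.34e-38, adjusted p = 0.000132 with an estimated correlation). They included Klrg1 (-2.55), Cx3cr1 (-1.93), a chemokine receptor gene of effector cells, and Prdm1 (-1.02), which encodes the effector regulator Blimp-1. All 6 genes of the NK cell marker list, which shares Gzma with the cytotoxic list, were lower as well, with and without adjustment over the list alone (adjusted p = 2.77e-16, adjusted p = 3.02e-05 with an estimated correlation), but fewer were without Th1 sample 2. The mean of this list was 6.99 and 7.17 in the Th1 samples and 5.70 to 5.89 in the Th17 samples. In Th1 samples of day 5 it was 5.88 to 6.18. Which cells carried the NK cell and cytotoxic transcripts of the day 15 Th1 samples was not tested. Of the 10 inhibitory receptors 7 were lower, such as Entpd1, which encodes CD39, at -1.38 (8 lower and 1 higher adjusted over the list alone, adjusted p = 3.83e-11, adjusted p = 0.00506 with an estimated correlation), and without Th1 sample 2 the count was 3. The Th1 program had 5 of 13 genes lower and 0 higher (9 and 0 adjusted over the list alone, adjusted p = 8.35e-09, adjusted p = 0.0099 with an estimated correlation). Those 5 became 0 without Th1 sample 1, 1 without Th1 sample 2, 2 without Th17 sample 2 and 3 without Th17 sample 3. Of the 17 pro-apoptotic genes 4 were lower (5 adjusted over the list alone, adjusted p = 9.33e-07, adjusted p = 0.0199 with an estimated correlation), with 2 without Th1 sample 1, 0 without Th1 sample 2 and 2 without Th17 sample 2.

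Among the 14 Wnt and stem-like memory genes, Ccr7 and Satb1 (0.83), a chromatin organiser, were higher in Th17 cells at day 15 (6 adjusted over the list alone, adjusted p = 7.52e-05, adjusted p = 0.0864 with an estimated correlation). Cell cycle genes lay higher in Th17 cells, 6 of 24 with limma and 17 adjusted over the list alone (adjusted p = 9.12e-14, adjusted p = 0.143 with an estimated correlation), though 0 passed without Th1 sample 2 and 10 without Th17 sample 3. The Th17 program had 3 of 12 genes higher and 0 lower (3 and 2 adjusted over the list alone), with a median of -0.03, a mean of 0.01 and an upward test (adjusted p = 0.695), and 1 was higher without Th1 sample 1. All arrays of day 15 carried erythroid marker transcripts, with a mean of the 6 markers of 9.52 and 9.86 in Th1 and 8.94 to 9.75 in Th17 samples. As a list they lay lower in Th17 samples, with a median of -0.25 (1 lower with limma and adjusted over the list alone, adjusted p = 0.0127, adjusted p = 0.362 with an estimated correlation). That call was lost without Th1 sample 1 (adjusted p = 0.467) or Th17 sample 3 (0.159). No erythroid gene passed without either of these, Th1 sample 2 or Th17 sample 2, and 2 did without Th17 sample 1. Dendritic and MHC class II markers lay lower too, with a median of -0.10 (1 of 9 lower, 0 without Th1 sample 2, 1 adjusted over the list alone, adjusted p = 0.00945, adjusted p = 0.0864 with an estimated correlation). The test called 828 genes, 374 higher and 454 lower in Th17 cells, 165 of them at least 2-fold. The larger side turned without Th17 sample 3 (448 higher, 373 lower), without Th1 sample 2 (152, 131) and with the erythroid marker mean as a covariate (493, 376). It called 421 without Th1 sample 1, 283 without Th1 sample 2 and 1581 with array weights.

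After restimulation at day 15, chemokine and cytokine genes were among those lower in Th17 than in Th1 cells, but the list means of the arrays overlapped between the types. The cytokine list mean was 10.96 and 9.78 in Th1 samples 1 and 2. In Th17 samples 1 to 4 it was 9.92, 8.32, 8.70 and 8.49. Ccl3 (probe set 10389231), which encodes a chemokine that attracts leukocytes to inflamed sites, stood at 10.07 ± 1.62 in Th17 (n = 4) and 13.37 ± 0.59 in Th1 cells (n = 2, adjusted p = 0.000432, 0.081 with only the compared groups in the model, the highest over its alternatives). Its neighbour Ccl4 stood at 7.71 ± 1.19 and 11.40 ± 1.56 (adjusted p = 7.96e-05), and Xcl1, a chemokine that attracts dendritic cells, at 7.43 ± 0.56 and 10.31 ± 1.29 (adjusted p = 1.63e-05). Pdcd1, which encodes the inhibitory receptor PD-1, was 3.48-fold lower in Th17 cells (adjusted p = 2.25e-05). Dapl1 (3.81), Ccr7 (1.57) and Il23r (1.56) were higher in Th17 cells, and Gzma (-2.17), Gzmb (-1.43) and Klrg1 (-2.27) were lower.

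Of 27 cytokine and chemokine genes 15 were lower in restimulated Th17 cells and 0 higher (18 and 2 adjusted over the list alone, adjusted p = 3.21e-12, adjusted p = 0.0639 with an estimated correlation), and 5 without Th1 sample 1. The cytotoxic list had 13 of 17 genes lower (14 adjusted over the list alone, adjusted p = 5.59e-26, adjusted p = 0.00111 with an estimated correlation). The NK cell marker mean was lower too, at 5.62 to 5.78 in Th17 samples against 6.61 and 6.75 in Th1 samples. Inhibitory receptors were lower in 6 of 10 (7 lower and 1 higher adjusted over the list alone, adjusted p = 8.94e-10, adjusted p = 0.00928 with an estimated correlation). The Treg list, genes of regulatory T cells, had 5 of 8 lower, Lrrc32 (-1.67) among them (6 adjusted over the list alone, adjusted p = 2.07e-06, adjusted p = 0.0371 with an estimated correlation). That count was 2 without Th1 sample 2 and 3 without Th17 sample 2 or Th17 sample 4. Cell cycle genes were higher in 20 of 24, such as Cdc20 (0.78), needed for chromosome segregation (22 adjusted over the list alone, adjusted p = 5.21e-24, adjusted p = 0.0371 with an estimated correlation), and in 9 without Th1 sample 1. Beside these groups, the erythroid markers differed: all 6 were lower in restimulated Th17 cells, with a median of -0.87 (6 adjusted over the list alone, adjusted p = 4.52e-08, adjusted p = 0.0371 with an estimated correlation), and 1 was without Th1 sample 1. Dendritic and MHC class II markers were lower in 3 of 9 (3 adjusted over the list alone, adjusted p = 0.00488, adjusted p = 0.0541 with an estimated correlation), a call lost without Th1 sample 1 (adjusted p = 0.0587), where 1 gene was lower. Heat shock and handling stress genes lay higher, with 0 passing alone with limma or over the list alone (adjusted p = 0.00386, adjusted p = 0.224 with an estimated correlation), a call lost without Th1 sample 2 (adjusted p = 0.367) or Th17 sample 1 (0.058). The call covered 1282 genes, 688 higher and 594 lower, with 224 at least 2-fold. The larger side turned with the replicate block (412 higher, 532 lower) and without Th1 sample 1 (298, 321) or Th17 sample 4 (510, 519). With the block the comparison rested on samples 1 and 2 of each type. It covered 619 without Th1 sample 1, 2391 without Th1 sample 2, 394 with only the compared groups in the model and 337 with array weights.

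To ask whether the Th17 minus Th1 difference itself changed between the days, the unstimulated groups were put into an interaction test. Across genes the differences at day 5 and day 15 had a Pearson r of 0.38 but a Spearman rho of 0.03 (19938 genes, which are not independent replicates). Of the 460 genes higher in Th17 cells at day 5, 179 were higher at day 15, where 8.6 would be shared if the calls were independent, and of the 264 lower ones 117 were lower at day 15, against 6.0. The difference in Il23r shrank by day 15, with an interaction of -2.06 (adjusted p = 0.00013), and that in Dapl1 grew by 2.43 (adjusted p = 0.000574). The Klk1b11 difference moved by 3.70 (adjusted p = 1.06e-06). Gzmb fell further behind in Th17 cells, with an interaction of -1.46 (adjusted p = 0.0104), though without Th1 sample 2 of day 15 it was -1.41 (adjusted p = 0.102). The cell cycle list mean moved up. It was 11.14 to 11.27 in Th17 and 11.35 to 11.47 in Th1 samples at day 5. At day 15 it was 10.51 to 10.87 in Th17 and 10.50 and 10.20 in Th1 samples. The cytotoxic list moved down, with 6 of 17 genes lower (11 lower and 1 higher adjusted over the list alone, adjusted p = 2.82e-15, adjusted p = 0.015 with an estimated correlation). Of the NK cell markers 4 of 6 moved down (6 adjusted over the list alone, adjusted p = 2.82e-15, adjusted p = 4.94e-05 with an estimated correlation). Markers of myeloid, dendritic and erythroid cells moved down as lists, with 0 genes passing alone with limma. The myeloid list had a median of -0.44 (1 lower and 1 higher adjusted over the list alone, adjusted p = 0.0149, adjusted p = 0.437 with an estimated correlation). It lost its call without Th17 sample 1 of day 5 (adjusted p = 0.567) or Th17 sample 3 of day 15 (0.0636). The dendritic and MHC class II list had a median of -0.33 (3 lower adjusted over the list alone, adjusted p = 0.00588, adjusted p = 0.0712 with an estimated correlation). The erythroid list had a median of -0.48 (1 lower adjusted over the list alone, adjusted p = 0.000153, adjusted p = 0.118 with an estimated correlation). Without Th1 sample 1 of day 15 the counts were 3 cytotoxic and 2 NK cell genes, and without Th1 sample 2 of day 15, 2 cytotoxic genes. The interaction was called for 227 genes, 115 up and 112 down (the larger side turned in 12 of 20 alternatives), 62 at least 2-fold. Among single omissions, the count was 34 without Th1 sample 2 of day 15, 151 without Th17 sample 2 of day 15 and 357 without Th17 sample 3 of day 15. It was 99, 136 and 122 without day 5 Th1 sample 1, Th1 sample 3 and Th17 sample 3. It was 374 with only the compared groups, 341 over genes above the median, 426 after cyclic loess and 1319 with array weights.

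**Figure D3:**
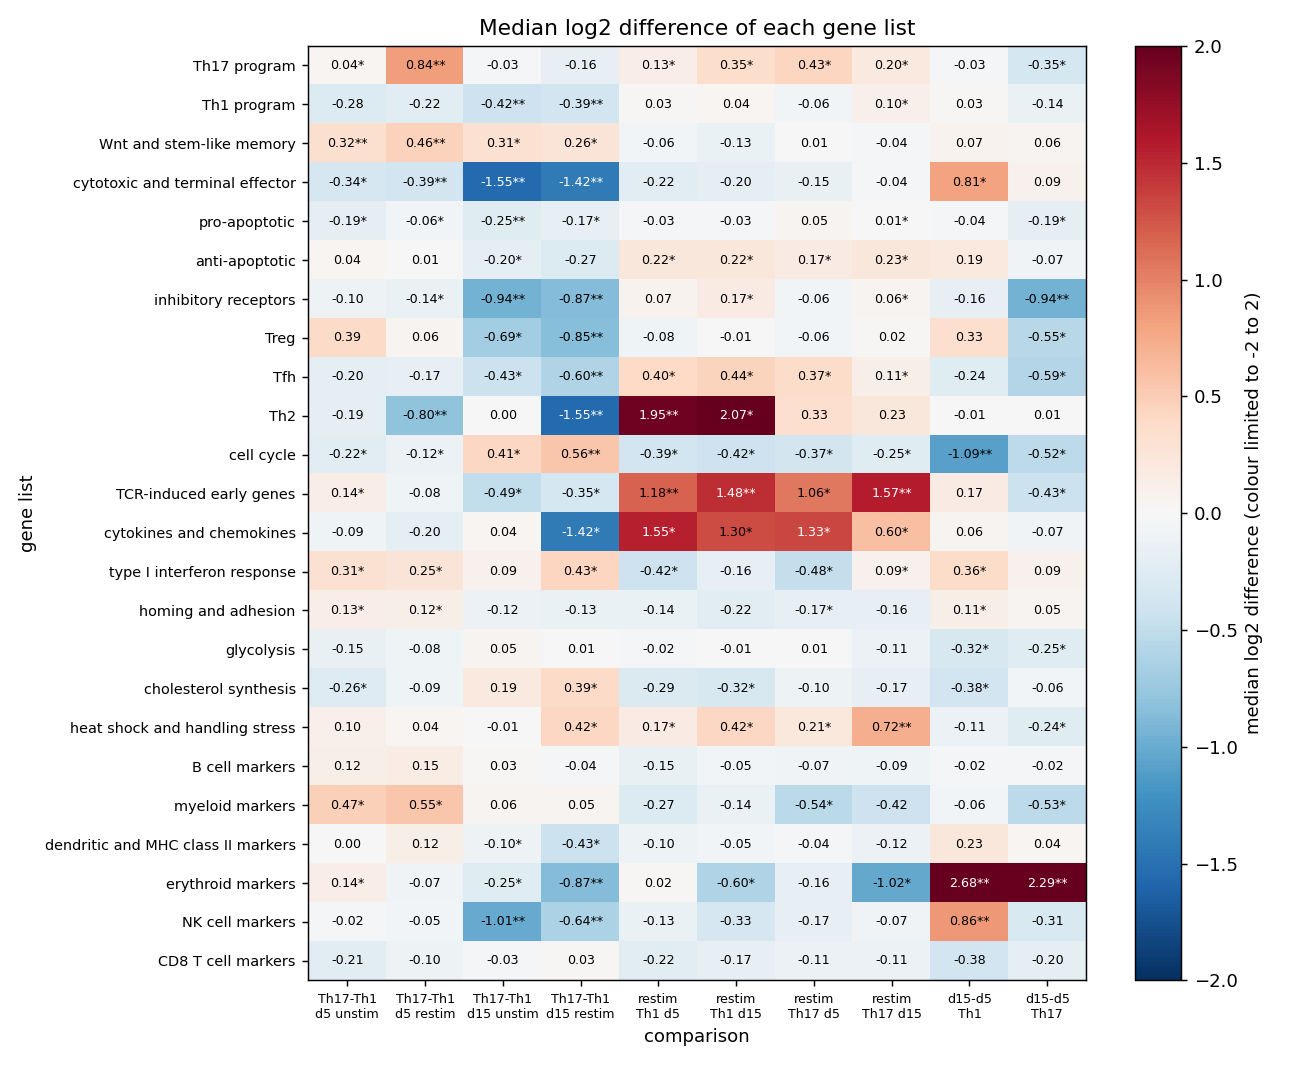
Median log2 difference of the 24 gene lists (vertical axis) in 10 comparisons (horizontal axis), with the colour scale limited to -2 and 2. One asterisk marks an adjusted p under 0.05 by camera and a pair of asterisks one that also holds with an estimated correlation: the cytotoxic list has a median of -1.55 for Th17 minus Th1 at day 15.

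Restimulation was then compared with no stimulation within each type at day 5. Il2 (probe set 10497878) rose 46.2-fold in Th1 cells, from 6.17 ± 0.11 to 11.70 ± 0.55 (n = 3 each, adjusted p = 9.06e-07), and 26.2-fold in Th17 cells, from 6.96 ± 0.49 to 11.67 ± 0.26 (n = 3 each, adjusted p = 1.12e-05). Il17a rose 10.5-fold in Th17 cells, from 6.88 ± 0.24 to 10.27 ± 0.05 (adjusted p = 1.18e-07), and Il17f 8.0-fold (adjusted p = 1.07e-10). In Th1 cells the log2 changes were 0.10 (adjusted p = 0.918) and 0.09 (adjusted p = 0.844). Nr4a1 (probe set 10427035), an orphan nuclear receptor gene switched on by the T cell receptor, rose by 2.99 in Th1 and 2.52 in Th17 cells. Klf2, which keeps resting T cells in circulation, fell by 1.01 in Th1 cells.

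The early genes induced through the T cell receptor rose in 16 of 21 members in Th1 cells (18 adjusted over the list alone, adjusted p = 1.34e-26, adjusted p = 0.0284 with an estimated correlation). In Th17 cells 14 rose (16 adjusted over the list alone, adjusted p = 1.54e-20, adjusted p = 0.0724 with an estimated correlation). Myeloid markers fell there in 2 of 14, with a median of -0.54 (2 adjusted over the list alone, adjusted p = 0.00312, adjusted p = 0.524 with an estimated correlation). The list lost its call, and 0 genes were lower, without unstimulated sample 1 (adjusted p = 0.53) or restimulated samples 2 (0.0771) or 3 (0.0895). The lower ones numbered 5 without unstimulated sample 2, 4 without restimulated sample 1 and 1 without both parts of sample 1. Nr4a3 (3.86 in Th1, 3.56 in Th17) and Egr2 (2.49, 2.13) were examples in both. Cytokine and chemokine genes rose in 19 of 27 members in Th1 cells, led by Il3 at 5.68 (20 adjusted over the list alone, adjusted p = 1.02e-20, adjusted p = 0.0671 with an estimated correlation), and in 17 in Th17 cells (20 adjusted over the list alone, adjusted p = 7.72e-20, adjusted p = 0.077 with an estimated correlation). The Th2 list rose in Th1 cells with 4 of 7 members, including Il13 (4.10) and Il4 (3.38) (4 adjusted over the list alone, adjusted p = 4.23e-05, adjusted p = 0.0284 with an estimated correlation). Anti-apoptotic genes rose in Th1 cells in 3 of 10 members, such as Bcl2l1 at 1.06 (3 adjusted over the list alone, adjusted p = 0.000764, adjusted p = 0.288 with an estimated correlation).

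Cell cycle genes fell in Th1 cells in 14 of 24 members, Plk1 (-0.85) and Bub1b (-0.90) among them (20 adjusted over the list alone, adjusted p = 7.05e-11, adjusted p = 0.288 with an estimated correlation). The count was 9 without unstimulated sample 1, 7 without unstimulated sample 3 and 8 without restimulated sample 3. Type I interferon response genes fell in 6 of 15 in Th1 cells, for example Ifit2 (-0.90), and 1, Oasl1, rose (9 and 2 adjusted over the list alone, adjusted p = 0.00115, adjusted p = 0.384 with an estimated correlation), with 3 lower without unstimulated sample 3 or restimulated sample 1. In Th1 cells 2597 genes were called, 811 higher and 1786 lower (1182 and 1311 after cyclic loess), 194 at least 2-fold. That count was 1566 and 1397 without unstimulated samples 1 and 3, 1630 and 1350 without restimulated samples 1 and 3. It was 4720 with only the compared groups and 5615 with array weights. In Th17 cells 1609 genes were called, 795 higher and 814 lower (656 and 1072 after centring), 158 at least 2-fold. More genes were higher than lower without unstimulated samples 1 (408, 253) or 3 (587, 401), restimulated samples 1 (496, 341) or 2 (892, 593), or both parts of sample 1 (227, 68). Without unstimulated sample 1 it was 661, without unstimulated sample 3 it was 988, without restimulated sample 1 it was 837, without restimulated sample 3 it was 921. Without both parts of sample 1, which had the highest myeloid marker mean, it was 295.

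Between the types the day 5 responses shared 511 higher genes (32.3 if independent) and 680 lower genes (72.9), and across all 19938 genes, which are not independent replicates, r was 0.83 and rho 0.72. The response differed between Th17 and Th1 cells for 4 genes with limma, 490 at an unadjusted p under 0.05. These were Il17a, with a response larger by 3.29 in Th17 cells (adjusted p = 0.00082), Il17f by 2.91 (adjusted p = 5.18e-07), the chemokine gene Ccl20 by 1.40 (adjusted p = 0.0159) and Dab2 by 1.27 (adjusted p = 0.0382). Ccl20 lost its call without unstimulated Th1 samples 1 (adjusted p = 0.0531) or 3 (0.075), unstimulated Th17 sample 1 (0.0897) or restimulated Th1 samples 1 (0.0887) or 3 (0.0585). Dab2 stood at 0.67 (adjusted p = 0.577) with the mean of its probe sets, with adjusted p-values of 0.00139 to 0.577 over its alternatives. It kept its call without restimulated Th1 sample 2 or either of restimulated Th17 samples 1 and 2. It lost the call without any other single array, at adjusted p-values of 0.06 to 0.218. The count was 2 without Th1 samples 1 or 3 of either part or unstimulated Th17 sample 1, 7 without restimulated Th1 sample 2, 9 without restimulated Th17 sample 2. It was 2 without both parts of Th17 sample 1, 12 with array weights and 1 over genes above the median. The Th2 list responded less in Th17 cells as a group, with a median difference of -0.46, though 0 genes passed alone with limma and 1 adjusted over the list alone (adjusted p = 8.5e-07, adjusted p = 0.00984 with an estimated correlation). The early genes had median responses of 1.05, 1.24 and 1.56 in Th1 samples 1 to 3. In Th17 samples 1 to 3 these were 1.00, 1.07 and 1.13. The erythroid list had a lower restimulated minus unstimulated difference in Th17 cells, by a median of -0.22 (1 lower adjusted over the list alone, adjusted p = 0.00081, adjusted p = 0.406 with an estimated correlation). In Th17 samples the mean of these markers was 6.69 to 6.81 unstimulated and 6.40 to 6.52 restimulated. In Th1 samples it was 6.46 to 6.59 and 6.44 to 6.58. Myeloid markers, whose mean fell with restimulation in both types, had a lower difference in Th17 cells too, by a median of -0.20 (0 adjusted over the list alone, adjusted p = 0.0277, adjusted p = 0.718 with an estimated correlation). That call was lost without unstimulated Th1 sample 1 (adjusted p = 0.171), restimulated Th1 sample 2 (0.0679) or restimulated Th17 samples 2 (0.644) or 3 (0.632), and turned upward without unstimulated Th17 sample 1 (0.244).

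The same comparison at day 15 asked how well the cells responded after longer residence. Il2 rose 30.7-fold in Th1 cells, from 6.74 ± 0.10 to 11.68 ± 0.97 (n = 2 each, adjusted p = 0.000128), and 6.87-fold in Th17 cells, from 6.78 ± 0.14 to 9.56 ± 1.66 (n = 4 each, adjusted p = 0.000279). Between same-numbered arrays Il2 differed by 5.56 and 4.33 in Th1 and by 5.04, 1.41, 3.00 and 1.65 in Th17 cells, numbers 1 to 4. These are not known to be parts of 1 sample, since the deviations of same-numbered Th17 arrays did not pair at day 15 (correlations of 0, 0.21, -0.13 and -0.16). Ifng (probe set 10366586) rose in Th17 cells by 1.20, from 11.12 ± 0.31 to 12.32 ± 0.62 (adjusted p = 0.0024). Il17a rose there by 1.02 (adjusted p = 0.00801), a value that was 0.56 (adjusted p = 0.00181) without restimulated sample 1 and the gene was not called with only the compared groups. Nr4a2 rose 20.3-fold in Th17 cells, from 7.51 ± 0.43 to 11.85 ± 0.60 (adjusted p = 4.06e-11), and by 3.91 in Th1 cells.

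Early genes rose in 16 of 21 members in Th1 (19 adjusted over the list alone, adjusted p = 1.61e-31, adjusted p = 0.0288 with an estimated correlation) and 18 in Th17 cells (18 adjusted over the list alone, adjusted p = 1.45e-32, adjusted p = 0.025 with an estimated correlation). Cytokine and chemokine genes rose in 19 of 27 in Th1 cells (23 adjusted over the list alone, adjusted p = 1.45e-22, adjusted p = 0.0506 with an estimated correlation), among them Il13 (5.05), but in 7 without either part of sample 1 and 10 without unstimulated sample 2. In Th17 cells 11 rose and 1 fell (11 and 1 adjusted over the list alone, adjusted p = 1.62e-09, adjusted p = 0.255 with an estimated correlation), with 7 higher without unstimulated sample 2. Heat shock and handling stress genes rose in Th17 cells in 7 of 9, Hspa1a, a stress-induced chaperone gene, reaching 12.55 ± 0.06 from 8.79 ± 1.59 (8 adjusted over the list alone, adjusted p = 1.61e-12, adjusted p = 0.0259 with an estimated correlation). In Th1 cells 3 of these genes rose (4 adjusted over the list alone, adjusted p = 1.55e-06, adjusted p = 0.131 with an estimated correlation), 1 without either part of sample 1 and 2 without unstimulated sample 2. At day 5 the list rose as well, with 2 genes in Th1 (adjusted p = 0.000758, adjusted p = 0.288 with an estimated correlation) and 1 in Th17 cells (adjusted p = 0.014, adjusted p = 0.504 with an estimated correlation). The last lost its call without unstimulated sample 1 (adjusted p = 0.0818) or restimulated sample 3 (0.0561). All 6 erythroid markers fell with restimulation in Th17 samples, with a median of -1.02 (6 adjusted over the list alone, adjusted p = 2.56e-07, adjusted p = 0.1 with an estimated correlation), Car1 going from 12.08 ± 0.30 to 10.21 ± 0.48. In Th1 cells 3 fell, with a median of -0.60 (3 adjusted over the list alone, adjusted p = 0.00373, adjusted p = 0.26 with an estimated correlation). These were 0 without unstimulated sample 1 (adjusted p = 0.131), 1 without unstimulated sample 2 and 1 without restimulated sample 2 (adjusted p = 0.41). In Th1 cells 1453 genes were called, 529 higher and 924 lower, 200 at least 2-fold. The larger share of lower genes did not hold after cyclic loess (796 higher and 795 lower) or without restimulated sample 1 (463 and 305) or unstimulated sample 1 (176 and 167). It turned as well with only the compared groups (39 and 3), array weights (185 and 144) and the erythroid marker mean as a covariate (256 and 103). That number was 343 and 447 without unstimulated samples 1 and 2, 768 and 2647 without restimulated samples 1 and 2. It was 42 with only the compared groups, 329 with array weights and 359 with the erythroid marker mean as a covariate. In Th17 cells 3499 were called, 1293 higher and 2206 lower (2098 and 1671 after cyclic loess), 271 at least 2-fold. This count was 2204 when only the compared groups were used and 1424 with the erythroid marker mean as a covariate.

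No single gene responded differently between the types at day 15: limma called 0, with 1216 at an unadjusted p under 0.05. Array weights also gave 0, while a model of only the compared groups, one with the replicate number as a block and one with a random block gave 1 each. Without restimulated Th1 sample 2 the count was 272, and without restimulated Th17 sample 1 it was 12. Omitting restimulated Th1 sample 1 or unstimulated Th17 sample 3 gave 1, and of either part of Th17 sample 4 gave 2. The Il2 response was smaller in Th17 cells by -2.17 (adjusted p = 0.775), or -2.95 (adjusted p = 0.0163) without restimulated Th17 sample 1. As a group the 27 cytokine and chemokine genes responded less in Th17 cells, with a mean difference of -1.21 (12 lower adjusted over the list alone, adjusted p = 5.83e-09, adjusted p = 0.312 with an estimated correlation), but the adjusted p was 0.13 without restimulated Th1 sample 1. Erythroid markers, which fell with restimulation in both types, fell further in Th17 cells, with a median difference of -0.52 (2 lower adjusted over the list alone, adjusted p = 0.000726, adjusted p = 0.312 with an estimated correlation). This call did not hold without the same array. Heat shock and handling stress genes responded more, with a median of 0.29 (0 adjusted over the list alone, adjusted p = 0.00241, adjusted p = 0.391 with an estimated correlation). That call was lost without unstimulated Th1 sample 1 (adjusted p = 0.0906), restimulated Th1 sample 2 (0.392) or restimulated Th17 sample 1 (0.0615). The early genes had a median difference of 0.05 and a mean of 0.00 (adjusted p = 0.841). Their direction hung on 1 Th1 array: the median was 0.27 in an upward test without restimulated Th1 sample 1 (adjusted p = 0.000232) and -0.27 in a downward test without restimulated Th1 sample 2 (adjusted p = 0.00941).

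**Figure D4:**
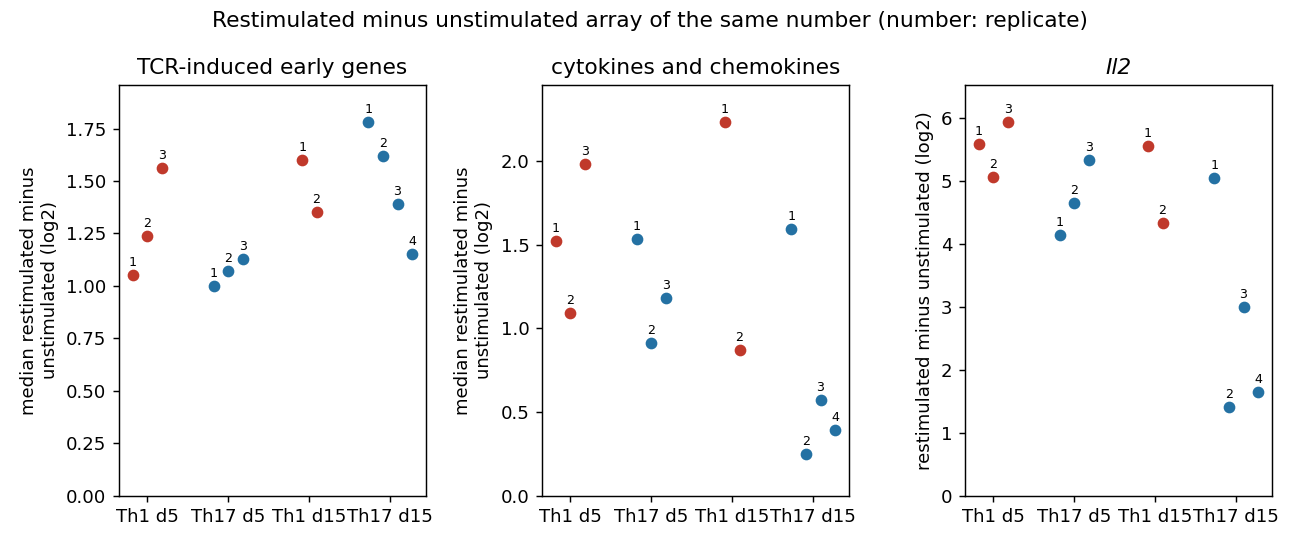
Response to restimulation (log2, restimulated minus unstimulated array of the same number) of the early gene list and the cytokine list as medians, and of Il2, at day 5 and day 15. At day 15 equal numbers are not known to mark parts of 1 sample. Red marks Th1 and blue Th17: the Il2 response runs from 1.41 to 5.04 in Th17 cells at day 15, and from 4.33 to 5.93 in Th1 cells over both days.

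Within Th1 cells, day 15 was compared with day 5 without restimulation to follow the cells as they persisted. Aurkb (probe set 10377405), a mitotic kinase gene, fell from 12.10 ± 0.06 at day 5 (n = 3) to 10.63 ± 0.38 at day 15 (n = 2, adjusted p = 1.71e-07). Klrk1, which encodes the activating receptor NKG2D, rose 5.98-fold, from 7.27 ± 0.19 to 9.85 ± 0.23 (adjusted p = 2.71e-10). Il7r rose by 1.08 and Bcl2 by 0.90. Gzmb (-0.28, adjusted p = 0.488), Ifng (-0.22, adjusted p = 0.781) and Tbx21 (0.16, adjusted p = 0.723), the gene of the Th1 regulator T-bet, did not pass. Erythroid transcripts rose with time: Car1 (probe set 10497337), a carbonic anhydrase gene of red blood cell precursors, went from 6.20 ± 0.14 to 12.06 ± 0.09 (adjusted p = 5.09e-14).

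All 24 cell cycle genes fell in Th1 cells, with a median of -1.09 (24 adjusted over the list alone, adjusted p = 1.75e-32, adjusted p = 0.0378 with an estimated correlation). Cytotoxic and terminal effector genes rose in 8 of 17, such as S1pr5 (2.14) and Klrd1 (2.08), and 1 fell (11 and 1 adjusted over the list alone, adjusted p = 6.18e-07, adjusted p = 0.1 with an estimated correlation). NK cell markers rose in 4 of 6, Klre1 (1.98) among them (5 adjusted over the list alone, adjusted p = 1.43e-06, adjusted p = 0.00378 with an estimated correlation). Glycolysis genes fell in 8 of 14, including Hk2 (-1.02) and Pgk1 (-0.80) (9 adjusted over the list alone, adjusted p = 2.59e-06, adjusted p = 0.1 with an estimated correlation), and in 5 without day 15 sample 1. Cholesterol synthesis genes fell in 6 of 12 (6 adjusted over the list alone, adjusted p = 0.000996, adjusted p = 0.237 with an estimated correlation), in 3 without day 15 sample 1 and 0 without day 15 sample 2. All 6 erythroid markers rose, with a median of 2.68 (6 adjusted over the list alone, adjusted p = 2.83e-18, adjusted p = 0.00378 with an estimated correlation). Other cell types moved less: the 9 B cell markers had a median of -0.02 (adjusted p = 0.813), the 9 dendritic and MHC class II markers 0.23 (2 higher with limma and adjusted over the list alone, 0 without day 5 sample 1 or day 15 sample 2, 1 without day 5 samples 2 or 3, adjusted p = 0.0595). The 2 CD8 T cell markers had a median of -0.38 (1 lower, 2 adjusted over the list alone, adjusted p = 0.0932). Of 3201 called genes 1462 were higher and 1739 lower at day 15 (2048 and 1784 after cyclic loess), with 445 at least 2-fold. The count was 1656 without day 15 sample 2, 5059 with only the compared groups, 4970 with array weights and 1213 with the erythroid marker mean as a covariate.

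Within Th17 cells the same days were compared without restimulation. Gzmb fell 3.34-fold, from 12.37 ± 0.38 at day 5 (n = 3) to 10.63 ± 0.18 at day 15 (n = 4, adjusted p = 4.54e-07), and Il23r fell from 9.16 ± 0.26 to 7.89 ± 0.19 (adjusted p = 7.26e-06). Tigit, an inhibitory receptor gene, fell from 12.17 ± 0.06 to 10.61 ± 0.25 (adjusted p = 7.99e-09). Klrg1 rose from 7.79 ± 0.30 to 9.29 ± 0.18 (adjusted p = 3.66e-07), and Dapl1 rose 13.2-fold, from 7.76 ± 0.34 to 11.48 ± 0.22 (adjusted p = 9.09e-11). Il7r (0.16, adjusted p = 0.525), Lef1 (-0.15, adjusted p = 0.322) and Il17a (-0.37, adjusted p = 0.419) did not pass.

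Inhibitory receptors fell in 6 of 10, Ctla4 (-1.56) and Cd160 (-1.33) among them (7 adjusted over the list alone, adjusted p = 9.6e-10, adjusted p = 0.0133 with an estimated correlation). Cell cycle genes fell in 17 of 24, with a median of -0.52 (22 adjusted over the list alone, adjusted p = 2.41e-18, adjusted p = 0.119 with an estimated correlation). Glycolysis genes fell in 4 of 14 (7 adjusted over the list alone, adjusted p = 6.77e-06, adjusted p = 0.119 with an estimated correlation). From the cytotoxic list 6 of 17 genes rose and 5 fell (7 and 5 adjusted over the list alone), with a median of 0.09, a mean of 0.06 and a downward test (adjusted p = 0.811), and 3 rose without day 5 sample 1. The risers included Klrg1 and Klrk1 (1.59). Those that fell included Gzmb, Gzmk (-1.44) and Prdm1 (-0.97). Early T cell receptor genes fell in 7 of 21, for example Cd69 (-0.86), a marker of recent activation (13 adjusted over the list alone, adjusted p = 5.14e-08, adjusted p = 0.231 with an estimated correlation), and in 3 without day 5 sample 3. The Tfh list, genes of follicular helper cells, fell in 4 of 8 (5 adjusted over the list alone, adjusted p = 0.000459, adjusted p = 0.119 with an estimated correlation), with 2 without day 5 sample 2 and 1 without day 5 sample 3. All 6 erythroid markers rose, with a median of 2.29 (6 adjusted over the list alone, adjusted p = 1.99e-19, adjusted p = 0.00466 with an estimated correlation), and S100a8, higher at day 5, fell by 2.31. The myeloid list moved down, with 3 of 14 genes lower and 1 higher (7 and 1 adjusted over the list alone, adjusted p = 0.00131, adjusted p = 0.384 with an estimated correlation). It lost its call without day 5 sample 1 (adjusted p = 0.255), and 2 genes were lower without that sample or day 15 samples 2, 3 or 4, and 5 without day 5 sample 2. Heat shock and handling stress genes fell in 2 of 9 (2 adjusted over the list alone, adjusted p = 0.0185, adjusted p = 0.384 with an estimated correlation), with no call as a list without day 5 samples 2 (adjusted p = 0.0637) or 3 (0.0864) or day 15 sample 3 (0.0647). Their count was 0 without any of these or day 15 sample 2 and 1 without day 15 sample 4. The call covered 1923 genes, 871 higher and 1052 lower (611 and 1839 after centring), 202 at least 2-fold. It covered 1082 without day 5 sample 1, 1272 without day 15 sample 3, 1115 without both parts of day 5 sample 1, 1147 with only the compared groups and 3279 with array weights. Th1 and Th17 cells shared 482 genes that rose (63.9 if independent) and 645 that fell (91.8), and the changes had an r of 0.65 and a rho of 0.52 across 19938 genes, which are not independent replicates.

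On day 0 the cultures were profiled on 1 array per group, so values are given without a test. Without restimulation Il17f was higher in the Th17 culture by 6.71, Il17a by 5.69 and Il23r by 4.95. Tbx21 (-4.53), Cxcr3 (-3.66), a chemokine receptor gene of Th1 cells, and Ifng (-2.35) were lower. The Th17 program had a median difference of 2.15, above all of 10000 random lists of like expression, and the Th1 program of -1.10, below all of them. Such ranks describe these arrays only: they hold no spread between samples and take genes as independent. The 15 interferon response genes were all lower in the Th17 culture, with a median of -1.34, but after restimulation 9 of 15 were higher, with a median of 0.12. The 14 myeloid markers were all higher in the Th17 culture, with a median of 1.64 and of 1.43 after restimulation, both above all random lists. Ngp, a neutrophil granule gene, was higher by 5.11. After restimulation Il17f (6.18) and Il17a (5.65) were higher in the Th17 culture, Lcn2 (3.74) as well, and Il4 (-5.17) lower. Across 19938 genes, which are not independent replicates, the day 0 difference had an r of 0.32 with that of unstimulated cells at day 5 (rho 0.13) and of 0.31 with that at day 15 (rho 0.22). The first r was 0.36 over the 9969 genes above the median.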

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

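The tests of a lower share of T cells, of the day 0 cultures, of a single Th17 sample, of weaker activation and of stronger restimulation in sample 1 were chosen after the results were seen, as were the covariates for marker means.

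In the day 15 Th17 groups, which held 4 samples, 76 values were tested for a sample far from the rest, and 5 stood apart where chance gives about 1 in 20. After restimulation, sample 1 had Ifng at 13.23 (others 11.95 to 12.13) and a Th2 list mean of 9.42 (others 8.59 to 8.71). Without restimulation, sample 3 had Il17a at 6.75 (others 6.39 to 6.45) and a cholesterol synthesis mean of 9.01 (others 9.33 to 9.40), and sample 2 had Il7r at 12.53 (others 12.39 to 12.40).

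The Th17 minus Th1 difference changed from day 5 to day 15, by the interaction test, in Klk1b11 (3.70, adjusted p = 1.06e-06), Dapl1 (2.43, 0.000574), Akr1c18 (2.04, 0.000853), Klk1b8 (1.61, 0.00131), Ifitm1 (-2.29, 0.00126), Cd24a (-2.25, 0.008), Olfr60 (-2.23, 0.000304) and Il23r (-2.06, 0.00013). Klk1b11, Klk1b8 and Olfr60 belong to families with close relatives, and signal shared between them was not tested. Gzmb (-1.46, 0.0104) lost its call without Th1 sample 2 of day 15 (-1.41, 0.102). Ctsg (1.57, 0.0138) lost it without Th1 sample 1 (0.0885) or 2 (0.0587) of day 15. Hspa1a (-3.83, 0.0272) lost it without day 5 Th1 samples 2 (0.0648) or 3 (0.0813), day 5 Th17 sample 3 (0.0888), day 15 Th1 samples 1 (0.147) or 2 (0.0863) or day 15 Th17 sample 2 (0.0547).

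The response to restimulation at day 5 differed between the types in Il17a (3.29), Il17f (2.91), Ccl20 (1.40) and Dab2 (1.27), the last pair depending on single arrays as described in the report. For these 4 genes the 10 splits of the samples are too few for a share under 0.05: 1 split, the real one, gave 4 genes and the highest other 0.

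Erythroid transcripts rose from day 5 to day 15 in both types, Car1 to 12.06 in Th1 and 12.08 in Th17 samples. Before transfer, on 1 array per culture, Car1 stood at 9.58 in the restimulated Th1 culture and 6.76 in the restimulated Th17 culture. The erythroid marker mean was 7.32 and 7.00 in the unstimulated Th1 and Th17 cultures, against 6.46 to 6.81 in unstimulated samples of day 5. If all other cells had risen as T cells fell, B cell markers would rise too, but their median was -0.02 in Th1 and -0.02 in Th17. Their means on these arrays, 5.97 to 6.25, lay under the array medians. This cannot decide on a lower share of T cells, as erythroid cells alone would lower it without raising B cell markers. Red cell precursors of the host, or their RNA, may be a source. A second erythroid set of 18 genes had medians of 0.86 in Th1 and 0.59 in Th17, between the bounds set in advance. Its members ran from -0.25 (Bpgm) to 3.83 (Cldn13) in Th1 and from 0.16 (Bpgm) to 3.29 (Cldn13) in Th17. Only Bpgm and Alad (-0.03) lay below 0, in Th1, and neither passed. By the bounds, host cells cannot be told apart from other sources. A sort on Thy1.2 is meant to remove such cells, but the purity of the samples is not shown here. With the erythroid mean as a covariate 19 of the 24 cell cycle genes that fell in Th1 cells stayed called, but every unstimulated day 15 array lay at least 2.13 above every unstimulated day 5 array in that mean (with restimulated arrays, 8.05 or more against 6.81 or less), so day and erythroid level cannot be told apart. A change within the T cells was not tested.

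Granulocyte genes were higher in the Th17 samples at day 5, such as S100a8 at 9.03 against 6.07. If all other cells had risen as T cells fell, macrophage genes would rise alike. These had a median of 0.16, which lies 0.68 below that of the second granulocyte set given below. This cannot decide on a lower share of T cells, as granulocytes alone would lower it without raising macrophage genes. Without both parts of Th17 sample 1, 5 of 7 granulocyte genes stayed called unstimulated, with a median of 2.20, while Ngp (2.22, adjusted p = 0.0618) and S100a9 (1.17, adjusted p = 0.0977) did not. These 7 were named for this same difference, so they cannot decide whether sample 1 alone carries it. In the myeloid list, fixed beforehand, the unstimulated means of Th17 samples 2 and 3 were 7.12 and 7.32, against 6.72 to 6.99 in Th1. Restimulated, that list lost its call without sample 1 (adjusted p = 0.718 by camera). A second granulocyte set had a median of 0.84 with 22 of 24 genes higher, but the Th17 culture already carried such signal at day 0: all 14 myeloid markers were higher (median 1.64, and 1.43 restimulated), and the second set had medians of 0.77 and 0.37. With 1 array per culture, host granulocytes, which a sort on Thy1.2 is meant to remove, cannot be told apart from signal carried over from the culture or a difference made by the polarization.

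Cytokine genes were lower in restimulated Th17 than Th1 samples at day 15. A weaker activation as a whole stays open. The early genes' response differed by a median of 0.05 and a mean of 0.00. All 27 cytokine genes had a median 1.05 below that of the early genes and a mean of -1.21, but without restimulated Th1 sample 1 the cytokine difference did not pass (adjusted p = 0.13), nor did it with an estimated correlation (0.312). The early median went to 0.27 without that array and to -0.27 without restimulated Th1 sample 2. A stronger restimulation of sample 1 cannot be told apart either: without restimulated sample 1 of both types the difference between types was -0.97 over all 27 genes (-1.42 with it), but 1 Th1 array is left. The Th17 polarization stays open as an untested explanation.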

How the results depend on the processing

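Covariates for marker means and leaving out both parts of Th17 sample 1 of day 5 were chosen after seeing the data, the rest was planned. No called value of a named gene reversed under the alternatives kept. The larger of the higher and lower counts changed side in 34 of 219 combinations of comparison and alternative, 18 of them with 1 array left out. These fell on the types at day 5 unstimulated (1 of 16) and at day 15 unstimulated (3 of 15) and restimulated (3 of 15), on restimulation in Th1 at day 15 (6 of 14) and in Th17 at day 5 (5 of 16) and day 15 (1 of 18), on time in Th1 (1 of 14) and Th17 (2 of 17) and on the interaction with day (12 of 20). List tests did when 1 array was left out. The early genes' response at day 15 (upward, adjusted p = 0.841) passed downward without restimulated Th1 sample 2 (0.00941) and upward without sample 1 (0.000232). The myeloid response at day 5 (downward, 0.0276) turned upward without unstimulated Th17 sample 1 (0.244). The erythroid covariate changed the sign of some named genes, mostly in day 15 against day 5, where it is confounded with day. Values of single genes with covariates were then left out, after these had been seen.

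Array weights gave 2159 genes for Th17 against Th1 at day 5 unstimulated (724 in the report), 1581 at day 15 unstimulated (828) and 337 restimulated (1282), 5615 for restimulation in Th1 at day 5 (2597) and 329 at day 15 (1453), 4970 and 3279 for time in Th1 (3201) and Th17 (1923), 1319 for the interaction with day (227) and 12 for the response at day 5 (4). A model of only the compared groups, with fewer arrays to estimate spread, gave 394 for the types at day 15 restimulated, 4720, 42 and 2204 for restimulation in Th1 at day 5, Th1 at day 15 and Th17 at day 15 (3499), 5059 and 1147 for time in Th1 and Th17, 374 for the interaction with day and 1 for the response at day 15 (0). The interaction with day had 341 genes above the median and 426 after cyclic loess. The response at day 5 had 1 above the median. The replicate block and the random block gave 1 each for the response at day 15. The myeloid covariate gave 427 for the types at day 5 unstimulated, and the erythroid covariate 359 and 1424 for restimulation at day 15 in Th1 and Th17 and 1213 for time in Th1. Without sample 1 there were 295 for restimulation in Th17 at day 5 (1609), 1115 for time in Th17 and 2 for the response at day 5. With an estimated correlation 34 list tests were called instead of 147 of 312. The day 0 correlation was 0.36 above the median (0.32). Apart from fewer arrays or genes, the cause was not tested.

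Leaving out 1 array gave ranges, for Th17 against Th1, of 444 to 703 at day 5 unstimulated, 488 to 899 restimulated (793 in the report), 283 to 828 at day 15 unstimulated and 619 to 2391 restimulated. For restimulation they were 1350 to 2164 and 661 to 1485 at day 5 in Th1 and Th17, and 343 to 2647 and 2390 to 4176 at day 15. For time they were 1656 to 2752 in Th1 and 1082 to 2302 in Th17, for the interaction with day 34 to 357, and for the response 2 to 9 at day 5 and 0 to 272 at day 15. The arrays behind values beyond 1.5 times are named in the report.

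Where replicate numbers paired arrays, the block ended the calls of Il21 (1.74) and Cxcr5 (-0.81) in Th1 restimulation and Id3 (0.70) between restimulated types at day 5, and added Bcl2 (-0.39) in Th17 restimulation. It changed no other call of a named gene there. Of 800 named values, called or not, 766 kept their status after cyclic loess, 754 after centring, 722 with array weights and 796 with the mean of probe sets. When 1 array was left out 4417 of 5140 did, and 707 lost a call. Values called in neither fit, such as those of panel genes that did not pass, count as kept. Scaling moved the balance of directions: restimulation in Th17 at day 15 had 1293 higher and 2206 lower genes, 2098 and 1671 after cyclic loess, and 1527 and 1594 after centring. Cyclic loess gave 1182 and 1311 for restimulation in Th1 at day 5 (811 and 1786), 796 and 795 at day 15 (529 and 924), and 2048 and 1784 for time in Th1 (1462 and 1739). Centring gave 656 and 1072 for restimulation in Th17 at day 5 (795 and 814) and 611 and 1839 for time in Th17 (871 and 1052).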

Other observations

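The splits were planned. The genes of the first paragraph follow the naming rule but were picked from it after their values were seen.

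Restimulation at day 15 also raised genes outside the early and cytokine lists in Th17 cells. Ctla4, an inhibitory receptor gene, rose by 1.20 and Ifit1, an interferon response gene, by 1.45, while Rhag, a gene of red cell membranes, fell by 1.95. In Th1 samples from day 5 to day 15, Rora, a transcription factor gene shared by several helper types, rose by 1.24, and the platelet chemokine gene Ppbp rose by 3.58. Which cells carried the Rhag and Ppbp transcripts was not tested.

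Splits of the same samples were compared with the real grouping. For restimulation in Th17 cells at day 15, 1 of 35 splits, the real one, gave as many as 3499 genes and the highest other gave 496. That share is under 0.05 if arrays can be exchanged freely. The samples were divided, however, and if equal numbers mark parts of 1 sample only the 8 splits that part all numbers apply. Their highest other count was 127, and 8 are too few for a share under 0.05. For day 15 against day 5 in Th17 cells, 1 of 35 gave as many as 1923, a share under 0.05. The highest other gave 1280. Without day 5 sample 1 the real grouping gave 1082, but on fewer arrays, and no split was rerun without that sample. The share holds for the full set of arrays only, and chance is not excluded there. With 3 samples in each group the 10 splits are too few for a share under 0.05. The real and highest other counts were 724 and 0 for the types at day 5 unstimulated, 793 and 1 restimulated, and 2597 and 1 for restimulation in Th1 and 1609 and 43 in Th17. In the last 3, where numbers pair the samples, 4 of the 10 splits part all numbers, and the highest other of these was 0.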
